A study of Mus musculus with 2 samples.

How the data were processed

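H3K4me2 was measured by ChIP-seq in embryonic liver of mouse at 11.5 days, in 2 biological replicates of 1 group. The labels give pooled male and female embryos of strain B6NCrl. Replicates were grouped by the replicate number in the labels, and no comparison between conditions is possible within the series.

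The deposited lists are in narrowPeak format on build mm10, per the deposited text listing. One list was made from each replicate alone, and the authors made a pooled list from both replicates and a replicated list from the pooled list and both replicates' lists, per the deposited text listing. The lists of replicate 1 and of the pool each drew on 2 further input files and that of replicate 2 on 1, per the same listing, which does not say what these files are. The aligner, the peak caller and its thresholds are not given in the sources used here. The deposited fold value of each peak is a ratio, read here as the authors' enrichment at the peak from the column order and range, and what it is relative to is not given in the sources used here. The deposited −log10 p-values and −log10 q-values are the authors' too. No p-value below 2.02 on the −log10 scale was found in any deposited list, and a q-value under 0.01 was reached by 87.9% of the replicate 1 peaks, 91.4% of the replicate 2 peaks and 94.3% of the replicated peaks. These values served only to describe, rank or filter peaks within a list. The lists hold no reads, so depth is unknown and no interval that needs it is given.

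Peaks on chromosomes 1 to 19, X and Y were used, which left out 12 peaks of replicate 1, 11 of replicate 2, 11 of the pooled list and 10 of the replicated list on unplaced scaffolds. All peaks lay within the chromosome lengths of GRCm38, the assembly that mm10 names. Genes and transcript starts came from GENCODE release M21: 21829 protein-coding genes with 54312 protein-coding starts. Symbols with several identifiers kept their longest gene, and 24 further records of such symbols were dropped. Coordinates are 1-based. Overlaps were computed with bedtools 2.31.1 and Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1), and plots with matplotlib 3.10.9.

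A peak was shared when at least 50% of its own length was covered by the other list. Shuffles (20, seeded) moved peaks within their chromosome. A peak was a promoter peak when it overlapped 2.5 kb on either side of a protein-coding start and distal otherwise, and distal peaks were sorted by their centre into UTR, other exon, intron and intergenic. A gene had a promoter peak when a replicated peak overlapped 1 kb on either side of any of its protein-coding starts. Breadth was the number of bases covered by replicated peaks within 5 kb on either side of the most 5' protein-coding start. The distal count was the number of distal peaks centred within 50 kb of that start. Domains were replicated peaks joined across gaps of up to 1 kb.

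The gene lists, tests and alternatives were fixed before the data were examined, except where the closing observations say otherwise. The 21 lists, taken from textbook knowledge, were hepatoblast identity, apolipoproteins and lipid transport, coagulation and complement proteins, mature hepatocyte metabolism, cholangiocyte, erythroid identity, globins, heme synthesis and iron, blood stem and progenitor, megakaryocyte, macrophage, endothelial, stellate and mesothelial, neuronal, muscle, germ cell and testis, lymphocyte, housekeeping and cell cycle genes, and Hox genes and olfactory receptors by symbol. Of the erythroid list 33 of 34 symbols were found in the annotation, and all symbols of the other lists were. Some genes stand in more than 1 list, such as Tfrc (erythroid and heme) and Mpl (blood stem and megakaryocyte). Promoter peaks were tested by two-sided Fisher's exact test against all other protein-coding genes. Breadth (lists with at least 3 marked genes) and distal counts were tested by two-sided permutation of list membership with 100000 resamples. Motifs were tested by two-sided Fisher's exact test against the same peaks moved to places on the same chromosome within 2 percentage points of GC, which gave 21671 pairs from 22193 distal peaks. Those places were not kept clear of other peaks. Each family was adjusted by the Benjamini-Hochberg method. The units of these tests are genes or peaks. Neighbouring genes share windows, so p-values of clustered lists (globins, Hox, olfactory receptors) are too small.

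The genes named were, for each list, up to 3 members with the most bases covered and up to 2 without a promoter peak in alphabetical order, the genes at the 10 longest domains, the nearest start of the 5 distal peaks with the highest fold, and 6 fixed loci. The alternatives were another overlap, the 50% of peaks with the higher fold, other windows, the most 5' start only, the pooled list, comparison genes matched on promoter CpG observed/expected ratio (500 bp on either side, 10 bins) or on gene density (up to 10 bins), tested by an exact sum of hypergeometric counts or by permutation within bins, and each replicate's own list in place of the replicated one. No test was made between the replicates.

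The procedures were tested on simulated data over 21829 genes. Of 2000 simulated overlaps 0 differed from a base-by-base count. Of 200 random lists of 22 genes 3.0% passed p = 0.05 in the promoter test (Fisher's exact), and of 200 lists with 95% marked against 70%, 89.0% did. Lists that differed only in CpG content passed in 99.0% of cases unmatched and in 2.0% matched. For distal counts 6.5% of random lists and 86.5% of lists raised by 2 peaks per gene passed. The motif test passed in 2.5% of random pairs and in 95.0% of pairs with a planted word.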

Results

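Dimethylation of histone H3 lysine 4 (H3K4me2), a mark of promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing in liver from mouse embryos at 11.5 days (strain B6NCrl). At this stage the liver bud holds hepatoblasts, the precursors of hepatocytes and bile duct cells, and is a site of blood formation. The design has 1 group with 2 biological replicates, each a pool of male and female embryos. Replicate 1 was pooled from 109 embryos, and the size of the pool is not given for replicate 2. The values are peak lists on mm10 (GRCm38) with a fold enrichment per peak that is the authors' own. The lists hold no read counts, so the depth is unknown. Tests over genes or peaks describe this peak set, since neither genes nor peaks are biological replicates.

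The first comparison asked how far the peaks of the 2 replicates coincide. On chromosomes 1 to 19, X and Y, replicate 1 had 64223 peaks over 55.9 Mb and replicate 2 had 41982 peaks over 46.6 Mb (mean 53102.5 ± 15726.8 peaks, SD, n = 2). Peaks of replicate 1 were narrower, with a median width of 423 bp against 799 bp, and had a median fold of 4.46 against 7.91 over all peaks. Across 34797 peaks of the authors' replicated list found in both replicates the order was the other way, with a median fold of 10.6 in replicate 1 and 9.58 in replicate 2. Of the replicate 1 peaks, 55.1% had at least 50% of their length covered by replicate 2 peaks, where the same peaks shuffled within chromosomes gave 1.93% ± 0.0498 (SD over 20 shuffles). In the other direction 91.4% of replicate 2 peaks were covered, against 2.17% after shuffling. The strong peaks were shared. In the 2 deciles of replicate 1 with the highest fold 100% were covered by replicate 2, and in the lowest decile 13.4%. At the promoters of protein-coding genes the replicates differed least: 15010 genes (68.8%) had a peak within 1 kb of a transcript start in replicate 1 and 14612 (66.9%) in replicate 2, and 14585 genes had one in both.

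**Figure D1:**
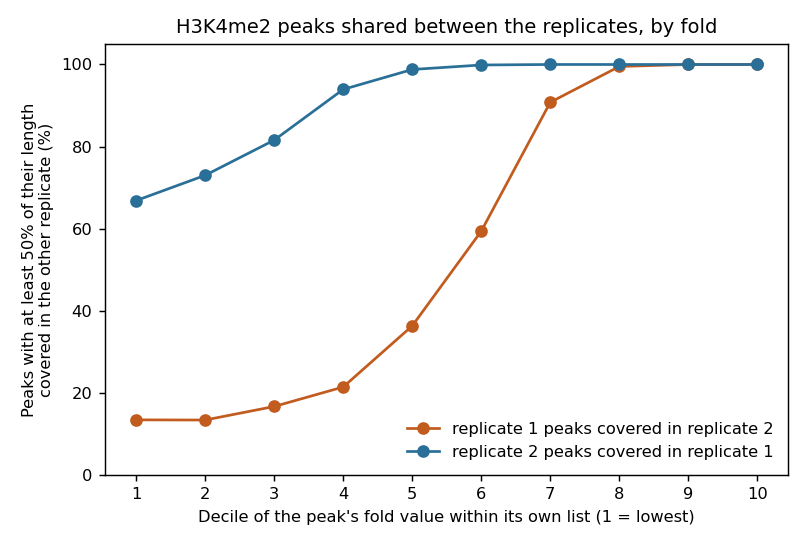
Share of each replicate's peaks (vertical axis, percent) with at least 50% of their length covered by the other replicate's peaks, by decile of fold enrichment within the replicate's own list (horizontal axis, lowest to highest). Replicate 1 went from 13.4% in the lowest decile to 100% in the highest, and replicate 2 from 66.8% to 100%.

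The authors' replicated list, used below as the main peak set, held 44237 peaks over 54.5 Mb, 89.6% of their pooled list. Of its peaks, 32574 (73.6%) had at least 50% of their length covered in both replicates' own lists. The remaining 11663 were weak and short, with a median fold of 3.42 and a median width of 311 bp, against 12.4 and 1209 bp. Across the peaks found in both replicates, the log2 fold values of the replicates correlated with a Pearson r of 0.907 and a Spearman rho of 0.900. That correlation is across peaks, which are not independent replicates.

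The next comparison asked where the marked regions lie. Promoters took 49.8% of the replicated peaks (22044 peaks overlapping 2.5 kb on either side of a protein-coding transcript start) against 7.33% ± 0.0956 (SD) over 20 shuffles, a ratio of 6.80. In the replicates' own lists the share was 43.4% and 55.7% (mean 49.6% ± 8.68, SD, n = 2). Promoter peaks were also the broadest and strongest class, with a median width of 1516 bp and a median fold of 17.1, and they held 70.8% of the marked bases. Introns took 26.5% of the peaks (shuffled 39.4%) with a median of 488 bp and a fold of 4.28, and intergenic sequence 17.9% (shuffled 49.4%) with 554.5 bp and a fold of 4.92. Chromosomes 11 and 19 had the most peaks per Mb, 30.4 and 24.3, and chromosome 7, with the most protein-coding genes (2007), had 20.0. X had 6.47 and Y, with 6 peaks in all, 0.0654. Among the 50% of peaks with the higher fold the promoter share was 73.2%.

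Which genes carried a promoter peak was then compared between 21 fixed gene lists and all other protein-coding genes, of which about 67.8% had one (14800 of 21829 genes). A gene is called marked where the replicated list has a peak there, and at unknown depth an unmarked gene is not shown to lack H3K4me2. All 27 hepatoblast identity genes had a promoter peak (100%, adjusted p = 0.000157), with replicates at 96.3% ± 5.24 (SD, n = 2, Fisher's exact test), and so had 32 of 33 erythroid identity genes (97% in the replicated list and in each replicate, adjusted p = 0.000333, Fisher's exact test). The erythroid exception was Car1, a carbonic anhydrase of red cells. The 20 housekeeping genes (adjusted p = 0.00136) and the 22 cell cycle genes (adjusted p = 0.000922) were all marked in both replicates, by Fisher's exact test.

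Genes of mature hepatocyte metabolism were marked far less often, a call that was lost against genes matched on promoter CpG content (23.3% against 34.3%). Only 7 of 30 mature hepatocyte metabolism genes had a promoter peak (23.3%, replicates 21.7% ± 2.36, SD, n = 2, Fisher's exact adjusted p = 5.11e-06). Among the unmarked were Cps1, which starts the urea cycle, and Abcb11, the bile salt export pump, while Glul, glutamine synthetase, and Ass1, a urea cycle enzyme, were marked. Coagulation and complement proteins, which hepatocytes secrete, did not pass the test (19 of 30, 63.3%, Fisher's exact adjusted p = 0.754), with F2 (prothrombin) and Fgg (fibrinogen gamma chain) marked and the complement genes C8b and C9 unmarked. Apolipoprotein and lipid transport genes stood at 11 of 16 (68.8%, Fisher's exact adjusted p = 1), with Apoe, Apom and Apoc1 marked and Apoa4 and Apoa5 unmarked. Genes of bile duct cells stood at 10 of 12 (83.3%, Fisher's exact adjusted p = 0.436), with the transcription factors Sox9, Sox4 and Hnf1b marked and Spp1 (osteopontin) and Tff2 unmarked.

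Among the other blood lists, heme synthesis and iron genes had 15 of 16 promoters marked (93.8%, Fisher's exact adjusted p = 0.0514). The 1 unmarked gene was Slc25a37, the mitochondrial iron importer, in whose start region 100% of 32-base words also occurred elsewhere in the genome. Blood stem and progenitor genes reached 18 of 23 (78.3%, adjusted p = 0.436) and megakaryocyte genes 13 of 16 (81.3%, adjusted p = 0.390), both by Fisher's exact test. Macrophage genes were marked in only 4 of 20 cases (20.0%, replicates 17.5% ± 3.54, SD, n = 2, Fisher's exact adjusted p = 7.98e-05), with Cd68 and the transcription factor Mafb marked and Adgre1 (F4/80) and Aif1 unmarked. Lymphocyte genes were also low, at 5 of 16 (31.3%, Fisher's exact adjusted p = 0.0104), with Cd19 and Cd3e unmarked. Globin genes stood at 5 of 8 (62.5%, Fisher's exact adjusted p = 0.754), with 75% in replicate 1 and 50% in replicate 2.

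Endothelial, stellate and mesothelial, and neuronal genes each had 18 of 22 promoters marked (81.8%, Fisher's exact adjusted p = 0.250). Among them were Dll4, a Notch ligand of arteries, and Wt1, a transcription factor of the mesothelium, while the endothelial gene Emcn had no promoter peak and Lyve1 had one in replicate 1's own list only. Hox genes, which pattern the body axis, reached 33 of 39 (84.6%, replicates 84.6% ± 10.9, SD, n = 2, Fisher's exact adjusted p = 0.0478), with Hoxa10 and Hoxa11 among the rest, each with a promoter peak in replicate 1's own list. Muscle, germ cell and olfactory genes were low. Muscle genes reached 5 of 18 (27.8%, Fisher's exact adjusted p = 0.00136), germ cell and testis genes 1 of 16 (6.25%, Fisher's exact adjusted p = 4.82e-06), and olfactory receptors 4 of 1091 (0.367%). In all, 11 of the 21 lists passed an adjusted p of 0.05 (5 higher, 6 lower; two-sided Fisher's exact test, Benjamini-Hochberg over the lists).

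Against genes matched on promoter CpG observed/expected ratio, 9 lists passed (7 higher, 2 lower), 4 of them shared with the unmatched test. The Hox, cell cycle, housekeeping, lymphocyte, macrophage, mature hepatocyte and muscle lists no longer passed. Coagulation (63.3% against 25.9%), globins (62.5% against 13%), megakaryocyte (81.3% against 38%), heme (93.8% against 67.9%) and endothelial genes (81.8% against 61.0%) then passed as higher in an exact test within CpG bins. The 1091 olfactory receptors, 0.367% of them marked, stayed among the comparison genes. Their own CpG-matched expectation was 13.5%, near that of the globins. How far the receptors lower the other expectations was not tested. Among the 50% of peaks with the higher fold the hepatoblast list lost its call, and coagulation (16.7% against 63.6%) and globin genes (0 of 8) passed as lower by Fisher's exact test, opposite to CpG matching. Heme genes passed as higher in 5 of 8 alternatives (also peaks covered in both replicates, the most 5' start only, a 2.5 kb window and replicate 1 alone), neuronal genes with a 2.5 kb window and replicate 1 alone and endothelial genes with replicate 1 alone. The Hox call was lost in 5 of 8 alternatives (CpG matching, peaks covered in both replicates, the most 5' start only, the higher fold and replicate 2 alone).

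**Figure D2:**
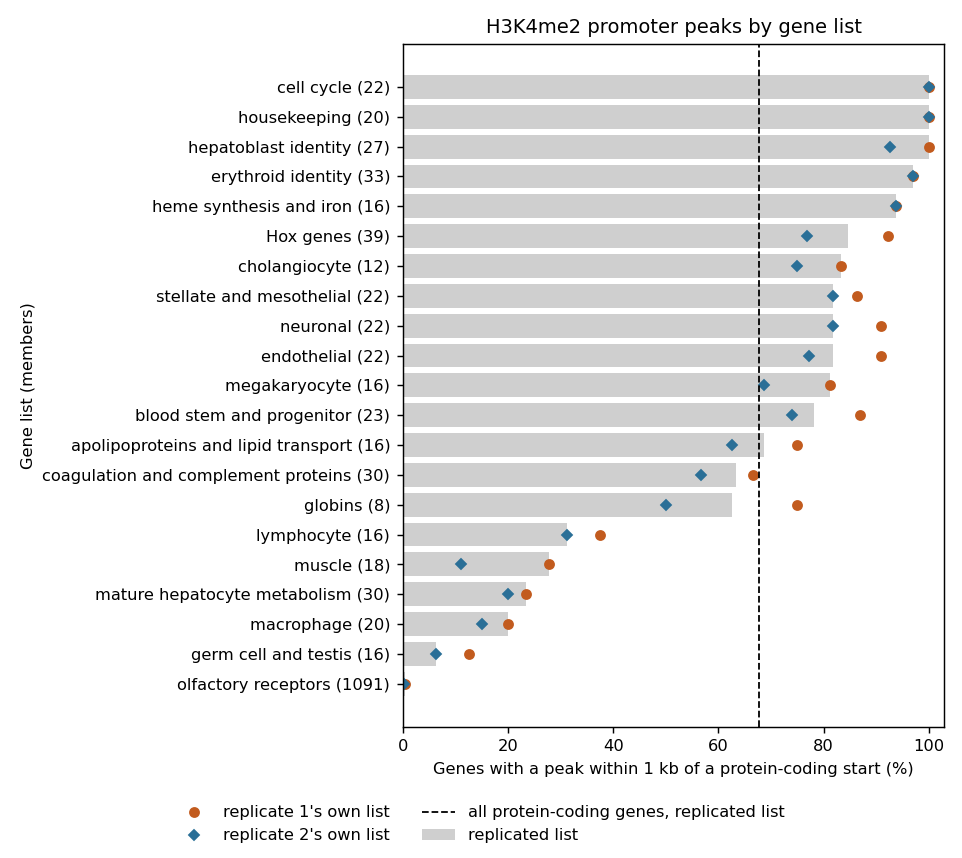
Share of the genes of each list with a peak within 1 kb of a transcript start (horizontal axis, percent), for the replicated peaks (bars) and for each replicate's own list (markers). Hepatoblast identity (100%) and erythroid identity (97%) lie near the top of the range and macrophage (20.0%) and germ cell and testis genes (6.25%) near the bottom.

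The breadth of the mark around the start separated the marked genes further. Among genes with a promoter peak the mean length covered within 5 kb on either side of the most 5' start was 2849 bp. It was highest in the heme and erythroid lists, at 5199 ± 384 bp (SEM over 15 genes) and 5143 ± 339 bp (SEM over 32 genes). Blood stem and progenitor genes had 4603 ± 527 bp and hepatoblast genes 3848 ± 458 bp (SEM over genes). Bcl11a, a repressor in the globin switch, had 9333 ± 89.1 bp covered (SD, n = 2 replicates), and Tal1 and Ldb1, partners in an erythroid transcription factor complex, had 7061 and 6977 bp in the replicated list. The heme enzymes Alad and Fech reached 7660 and 7622 bp. Of the stem cell regulators, Meis1 had 8038 bp, Fli1 7412 bp and Lyl1 7370 bp. Prox1, which hepatoblasts need to migrate out of the liver bud, led the hepatoblast list with 8582 ± 272 bp (SD, n = 2), followed by the transcription factors Tbx3 and Foxa1 with 7453 and 7279 bp in the replicated list.

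Housekeeping genes (4676 ± 386 bp, led by Tubb5) and cell cycle genes (4254 ± 257 bp, led by Ccnd1) were broad as well, and so were stellate and mesothelial genes (3919 ± 610 bp, SEM over genes), with Wt1 at 8009 bp and Pdgfra at 7859 bp. Neuronal genes were marked but narrow, at 1802 ± 251 bp, and coagulation genes had 2044 ± 219 bp (SEM over genes). The few marked genes of the mature hepatocyte (1585 bp, 7 genes), lymphocyte (1328 bp, 5 genes) and olfactory lists (419 bp, 4 genes) were narrow too. Genes entered by a peak at any start, while breadth was taken at the most 5' start. Only 2 lymphocyte and 2 olfactory genes had a peak within 1 kb of that start. The low breadth of these 2 lists can thus in part reflect the window. By permutation test, the smallest p that 100000 resamples can give, 2e-05 (adjusted 0.000133), was reached by the erythroid, heme and housekeeping lists. Permutation tests gave an adjusted p of 0.0003 for blood stem, 0.0006 for cell cycle, 0.0052 for hepatoblast, 0.0164 for stellate, 0.00509 for neuronal, 0.0289 for coagulation, 0.0289 for mature hepatocyte, 0.0262 for lymphocyte and 0.0006 for olfactory genes. Each of these 12 differences, of 20 lists tested, had the same direction in both replicates' own lists. Permutation tests did not separate Hox (3410 bp, adjusted p = 0.068), muscle (1569 bp, adjusted p = 0.068), apolipoprotein (3387 bp, adjusted p = 0.351), cholangiocyte (3339 bp, adjusted p = 0.400), globin (3212 bp, adjusted p = 0.676), macrophage (3032 bp, adjusted p = 0.847), megakaryocyte (2863 bp, adjusted p = 0.974) or endothelial genes (2826 bp, adjusted p = 0.974) from other genes. With CpG matching the coagulation, mature hepatocyte and lymphocyte calls were lost, with a 10 kb window those of coagulation, lymphocyte, neuronal and stellate genes, and in each of these settings Hox genes passed as broader. The coagulation and mature hepatocyte calls were also lost among peaks covered in both replicates (where Hox genes passed) and among the 50% with the higher fold, the stellate call with the higher fold and with replicate 1 alone, and the mature hepatocyte call with replicate 2 alone.

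Of the 10 longest marked domains, 3 lay over genes of the erythroid list, an overlap that was not tested. Joined across gaps of up to 1 kb, the replicated peaks formed 32155 domains with a median of 1276 bp. The longest, 28.4 kb on chromosome 8 (23033741 to 23062125, GRCm38), lay over Ank1, the ankyrin that ties the red cell membrane to its skeleton. Replicate 1 peaks covered 26.4 kb of it and replicate 2 peaks 23.5 kb. Second, at 23.5 kb on chromosome 8 (122280357 to 122303810), came Zfpm1, the GATA1 cofactor FOG1, and Lmo2, a bridging protein of the same erythroid complex, had 16.2 kb on chromosome 2 (103957076 to 103973278). Nr2f2, a nuclear receptor of veins and mesenchyme, had 23.1 kb on chromosome 7 (70347807 to 70370865), and Hoxb3 and Hoxb4 shared 20.1 kb on chromosome 11 (96308489 to 96328611). One domain of 16.6 kb on chromosome 8 (84964319 to 84980906) took in Prdx2, an abundant red cell peroxidase, Junb, Rnaseh2a and the gene model Gm49661. The other 4 of the 10 longest lay over Abt1 (18.3 kb), Gse1 (16.8 kb), Bahcc1 (16.5 kb) and Hnrnpf (15.6 kb). Gm20388, a gene model that spans both, overlapped the Zfpm1 and Gse1 domains, and 4931422A03Rik overlapped that of Lmo2.

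Distal peaks, those away from all protein-coding starts, were more numerous around globin, erythroid, heme, blood stem, megakaryocyte and hepatoblast genes, and also around Hox and housekeeping genes. Counting those centred within 50 kb of the gene's most 5' start, other genes averaged about 1.61. Globin genes averaged 8.13 ± 0.398 (SEM over 8 genes), erythroid genes 4.52 ± 0.928, blood stem and progenitor genes 4.30 ± 0.758, hepatoblast genes 3.52 ± 0.576, heme genes 3.44 ± 0.940 and megakaryocyte genes 3.19 ± 0.678 (SEM over genes). Hox genes averaged 5.69 ± 0.453 and housekeeping genes 3.9 ± 0.676, while olfactory receptors had 0.124 (SEM over genes 0.0207). Tbx3 had 15 such peaks, Fli1 12 and Fech 11. Replicate 1 had more such peaks than replicate 2 at every one of these lists, with 7.61 against 4.48 at erythroid genes and 5.59 against 3.11 at hepatoblast genes.

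By permutation test, 9 of 21 lists passed. The smallest p of 2e-05 (adjusted 0.000105) was reached by globin, Hox, erythroid and olfactory genes in the permutation test. The other permutation tests gave an adjusted p of 0.000168 for blood stem, 0.00091 for hepatoblast, 0.0012 for housekeeping, 0.0196 for heme and 0.0415 for megakaryocyte genes. Endothelial genes (2.68, adjusted p = 0.0972), cell cycle genes (2.59, adjusted p = 0.126) and stellate genes (2.36, adjusted p = 0.256) did not pass the permutation test. Neither did muscle (1.83), macrophage (1.8), apolipoprotein (1.75), neuronal (1.68), cholangiocyte (1.5), coagulation (1.4), germ cell (1.25), mature hepatocyte (1.1) and lymphocyte genes (0.875), with a permutation adjusted p between 0.281 and 0.995. Globin and Hox genes lie in clusters whose members count the same peaks, which makes their p too small: with 1 member per cluster the globins were too few to test. Hox genes still passed with 1 member per cluster, and their permutation adjusted p reached at most 0.0494 over 7 alternatives. The megakaryocyte call was lost in 5 of 7 alternatives (density-matched genes, peaks covered in both replicates, the 50% of peaks with the higher fold, a 100 kb window and replicate 2 alone), the heme call with the higher fold and at 100 kb, and the globin call with the higher fold.

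**Figure D3:**
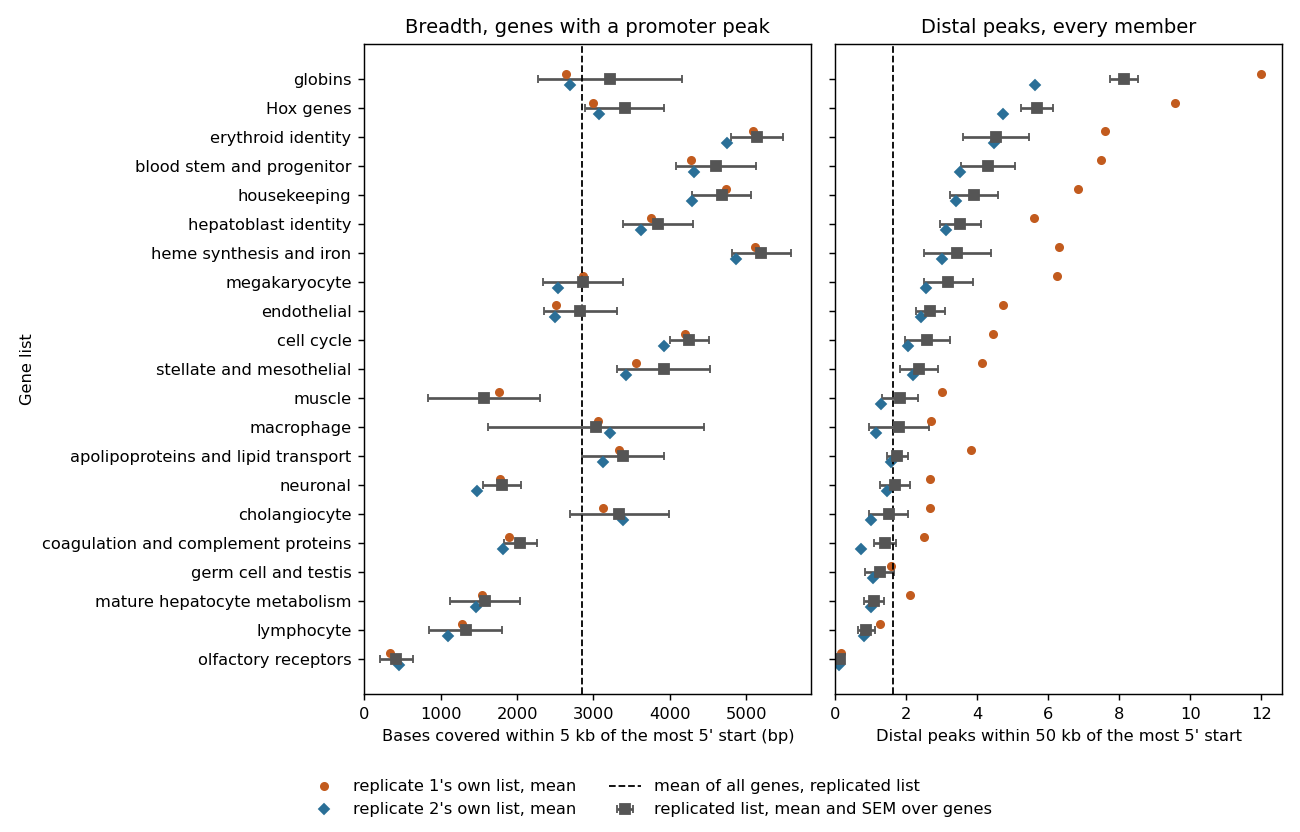
Mean bases covered within 5 kb of the start in genes with a promoter peak (left, bp) and mean distal peaks within 50 kb per gene (right), by list, with SEM over genes, each replicate's own mean and a dashed line at the mean of all genes. Erythroid genes lie above other genes in both, at 5143 bp and 4.52 peaks.

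The distal peaks with the highest fold lay both near and far from protein-coding starts. The highest, with a fold of 50.9 (44.4 and 44.2 in replicates 1 and 2), was intergenic on chromosome 14 (75833146 to 75836458), 8.63 kb from the start of Tpt1, a translationally controlled growth protein. The peak on chromosome 5 (106573830 to 106575376, fold 49.1) lay in an exon of the gene models Gm28050 and Gm28039. That on chromosome 6 (31215919 to 31218944, fold 48.7) lay in an intron of Lncpint, a long non-coding RNA, with the nearest protein-coding start, Mkln1, 180 kb away. An intergenic peak on chromosome 4 (132513439 to 132516307, fold 48.0) lay 2.94 kb from the start of Sesn2, a stress response gene, and a peak on chromosome 19 (46135379 to 46137755, fold 47.9) lay in an exon of Pitx3, 3.23 kb from its start. All 5 were strong in both replicates, with folds from 31.3 to 50.1.

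The sequence of the distal peaks was compared with places of the same width, chromosome and GC content. GATA sites (WGATAR, bound by GATA1 and its relatives) were present in 62.4% of 21671 distal peaks and in 55.6% of matched places (odds ratio 1.32, Fisher's exact adjusted p = 4.61e-46). Forkhead sites (TGTTTAC, bound by FOXA factors) were present in 10.1% against 7.10% (odds ratio 1.47, Fisher's exact adjusted p = 1.49e-28), and the CTCF core in 2.15% against 0.706% (odds ratio 3.09, adjusted p = 1.04e-37). The myogenic E-box CAGCTG and the neuronal E-box CAGATG had been set beforehand as comparison motifs. CAGCTG was higher as well, at 36.1% against 32.6% (odds ratio 1.17, Fisher's exact adjusted p = 3.61e-14), and CAGATG lower, at 39.4% against 42.5% (odds ratio 0.882, Fisher's exact adjusted p = 1.66e-10). A small p against these places is thus not particular to motifs of liver or blood factors. Sites of HNF4, a hepatocyte regulator, did not differ (2.07% against 2.03%, Fisher's exact adjusted p = 0.786). All were two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 6 motifs, and the 5 differences had the same direction in both replicates' own lists. HNF4 sites were higher in replicate 1's own distal peaks (1.51% against 1.23%, Fisher's exact adjusted p = 0.00158, range over 4 alternatives 0.00158 to 0.398) and in distal peaks covered in both replicates (2.53% against 2.14%, Fisher's exact adjusted p = 0.0378).

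At the globin loci the mark was spread over many short peaks. The beta-globin window on chromosome 7 (103762524 to 103903216, GRCm38) held 17 peaks, 8 of them at promoters, covering 9.58 kb. The strongest (103858663 to 103859526, fold 8.32) lay 5.45 kb upstream of Hbb-y, the embryonic beta-like globin, whose own start had no replicated peak within 5 kb. Of the 6 further replicated peaks upstream, the 3 with a fold above 5 lay at 103861175 to 103862017, 103865988 to 103866448 and 103870232 to 103870981, on the side where the locus control region is known to lie. The alpha-globin window on chromosome 11 (32226400 to 32347298) held 29 peaks over 21.9 kb. The strongest lay over starts of the neighbouring genes Mpg, Nprl3 and Sh3pxd2b, with folds of 28.5, 24.7 and 20.4. The 29 peaks also included some in introns of Nprl3, which house the alpha-globin enhancers, such as 32244942 to 32245765 (fold 8.43) and 32255679 to 32256294 (fold 6.71). The Hba-a1 and Hba-a2 start regions share sequence with other places, 74.5% and 80.6% of their 32-base words, so their own peaks are uncertain.

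The hepatoblast markers Afp (alpha-fetoprotein) and Alb (albumin) carried weak peaks. Their window on chromosome 5 (90410897 to 90558907) held 4 replicated peaks, all at promoters, over 3.46 kb. The Alb peaks at 90461556 to 90462225 and 90462436 to 90463460 had folds of 3.90 and 4.78, and the Afp peaks at 90491288 to 90492042 and 90492113 to 90493123 had 2.90 and 3.51. The window of Hnf4a, a regulator of hepatocyte identity, on chromosome 2 (163456808 to 163622910) held 9 peaks. The strongest lay over starts of the neighbouring genes Fitm2 (fold 27.3) and Ttpal (fold 17.7). Peaks at Hnf4a itself included one at its most 5' start (163506859 to 163507917, fold 4.68) and one in an intron (163535082 to 163535609, fold 11.7). The Apoa window on chromosome 9 (46178580 to 46321919) held 5 peaks, the strongest at Apoa1 (46228773 to 46231142, fold 25.5) and another in an intron of Sik3 (46214785 to 46216896, fold 10.8). Peaks of fold 18.7 and 20.4 in this window lay over starts of the neighbouring genes Zpr1 and Bud13. Apoa4 and Apoc3 in the same cluster had no replicated peak within 1 kb of a start, though Apoc3 had one in replicate 1. Gata1, the master regulator of red cells, carried a peak of fold 14.4 over a start inside the gene on chromosome X (7963641 to 7967588) and an intergenic peak of fold 7.58 lying 14.9 kb upstream (7992987 to 7993577). Replicates 1 and 2 had 12 and 5 peaks in the Afp and Alb window, 23 and 10 in the Hnf4a window, 8 and 7 in the Apoa window and 11 and 13 in the Gata1 window.

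**Figure D4:**
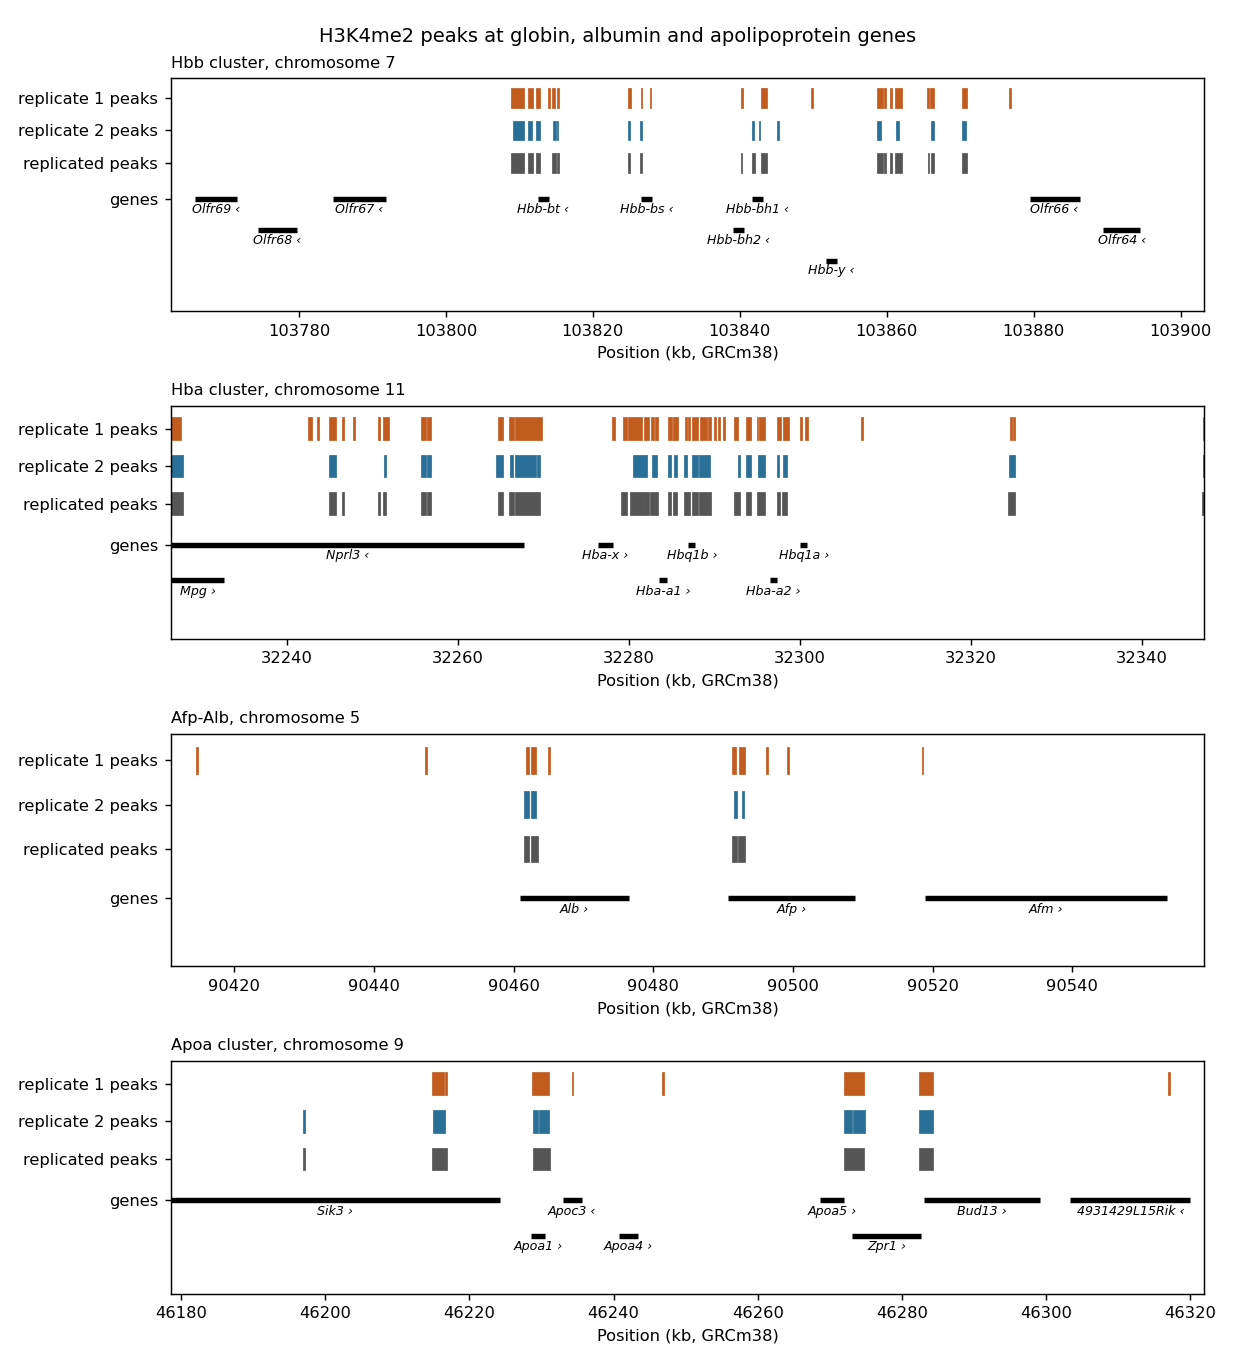
Peaks of replicate 1, of replicate 2 and of the replicated list (coloured blocks, drawn to scale) above the genes (black bars, arrows for the strand) in 4 of the fixed windows, with position in kb of GRCm38 on the horizontal axis. The replicated list had 17 peaks in the beta-globin window, 29 in the alpha-globin window, 4 in the Afp and Alb window and 5 in the Apoa window.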

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

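The alternatives that kept only replicated peaks covered by at least 50% in both replicates, or only 1 gene per cluster, were chosen after seeing the data. No paired analysis was possible because there is 1 group. The numbers of lists or motifs past the threshold stayed within 1.5 times in all 25 recounts, though not always with the same lists: 11 of 21 lists passed for promoter peaks (9 to 14 under the alternatives), 12 of 20 for breadth (9 to 11), 9 of 21 for distal peaks (6 to 9) and 5 of 6 motifs (5 to 6). Single lists kept direction and side of the threshold in 130 of 168 recounts for promoter peaks, 95 for breadth (4 reversed, 1 of which also lost its call, 3 gained the call and 13 lost it with the direction kept), 122 of 146 for distal peaks and 22 of 24 for motifs. The erythroid list stayed past the threshold in all 3 families under every alternative run. With the globins reduced to 1 gene per cluster, and with fewer than 3 marked genes in other lists, some recounts could not be made. Values without a test moved with the overlap rule: with any overlap 60.5% of replicate 1 peaks were shared, 94.8% of replicate 2 peaks and 78.7% of replicated peaks in both replicates. With both replicates' lists restricted to their 50% with the higher fold, 62.5% of 31536 replicate 1 peaks and 99.7% of 20977 replicate 2 peaks were shared, where the shorter list limits the first share. Of the replicated peaks with the higher fold 99.7% were covered in both replicates, and the promoter share rose to 73.2%, since weak peaks are left out. Reversed differences follow, in percentage points for promoter peaks, bp for breadth and peaks per gene for distal peaks, as list minus other genes. With CpG matching, promoter differences became 37.4 for coagulation, 49.5 for globins, -6.30 for neuronal and -4.43 for Hox genes, and breadth differences 243 for coagulation and 422 for endothelial genes. Among peaks covered in both replicates, they were -3.95 for apolipoproteins and -10.2 for megakaryocyte promoters, and -0.196 for macrophage and -0.0510 for muscle distal peaks. With the most 5' start only, apolipoproteins gave -2.76. Among the 50% with the higher fold, promoter differences were -19.8 for apolipoproteins, -13.5 for megakaryocyte, -4.43 for endothelial and -14.8 for Hox genes. Distal differences there were -0.0258 for apolipoproteins, -0.0132 for macrophage, -0.145 for stellate, -0.0744 for muscle, 0.0993 for germ cell and 0.0993 for lymphocyte genes. The 2.5 kb window gave -0.232 for apolipoproteins, 1.02 for coagulation and 18.5 for globins, and the 100 kb window gave distal differences of 0.225 for cholangiocyte and -0.374 for neuronal genes. Apolipoprotein distal differences were -0.119 with density matching and -0.0140 with 1 gene per cluster. With either replicate left out, promoter differences ranged from -4.44 to 6.24 for apolipoproteins and from -16.9 to 6.24 for globins, and breadth from -57.4 to 46.5 for megakaryocyte and from -176 to 100.3 for globins. Distal differences ranged from -0.223 to -0.193 for macrophage, -0.0954 to 0.107 for muscle and -0.212 to 0.0815 for neuronal genes. The cause was not tested. Depth is unknown, so a weak region outside a list cannot be called unmarked, which bears most on replicate 2 and on weak peaks.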

Other observations

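The tests of starts inside peaks, of shuffled motif words and of repeated sequence at starts were chosen only after the results were seen. Of 14245 protein-coding genes with a replicated peak within 1 kb of the most 5' start, 85.6% had that start inside a peak (86.6% in replicate 1 and 73.3% in replicate 2). Starts lay inside a peak less often for hepatoblast genes (18 of 27, 66.7%, adjusted p = 0.0381), coagulation and complement genes (10 of 18, 55.6%, adjusted p = 0.0184), heme genes (9 of 15, 60%, adjusted p = 0.0411) and globins (1 of 5, adjusted p = 0.0184), by two-sided Fisher's exact test with Benjamini-Hochberg adjustment. Macrophage and muscle genes each had 1 of 4 (Fisher's exact adjusted p = 0.0381). Erythroid (28 of 31), blood stem (14 of 18) and megakaryocyte genes (9 of 12) did not pass the test. Against genes of matched promoter CpG content no list passed the exact test (lowest adjusted p 0.109, for erythroid genes, 90.3% against 71.6%).

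The word AGATAA, one form of the GATA site, stood out from words of the same bases in another order. It was present in 34.9% of distal peaks and 23.8% of matched places, an odds ratio of 1.72 that was the highest of 30 arrangements, where the next reached 1.42 and the median of the others was 1.08. The forkhead word TGTTTAC, with an odds ratio of 1.47, ranked 24 of 210 arrangements, the highest at 1.93 and the median of the others at 1.06. Words above it held a CG, as CGTTTTA (1.93) does, except GTTATCT, GTTTATC and TTATCTG (GATA on the other strand) and GTTTACT. Places were matched on GC and not on CG pairs, so this rank does not decide whether the forkhead word stands out. Repeated sequence was examined at the starts of 425 listed genes, without the olfactory receptors. In 5 of them more than 50% of the 32-base words within 1 kb of the start occurred elsewhere: Slc25a37 (100%), Cyp2c29 (92.1%), Hba-a2 (80.6%), Hba-a1 (74.5%) and Kng1 (69.9%). Slc25a37, Cyp2c29 and Kng1 had no promoter peak, and these genes were named after their values were seen.

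Replicate 1 had 1.53 times as many peaks as replicate 2. A different mix of liver and blood cells in the pools was examined as a cause of this excess. The ratio of distal peaks per gene between the replicates was 1.70 at erythroid and 1.80 at hepatoblast genes. Their ratio of ratios was 0.943 (bootstrap 95% interval 0.730 to 1.24), so the excess was of similar size at both lists. A peak is called or not and its count need not follow the share of a cell type. A difference in mix could thus go unseen and stays open. It also stays open whether replicate 1's list admitted more weak peaks. Of its 28852 unshared peaks, 90.05% lay in the 50% of its list with the lower fold (Wilson 95% interval 89.7% to 90.4%, taking peaks as independent). A share of 90% had been set beforehand as the mark and under 75% as counter-evidence. Unshared peaks were weak in replicate 2's shorter list too (99.9% of 3612), so the share in replicate 1 cannot decide the question. Depth, the further input files and the caller's settings may each underlie the excess, and the lists do not separate them. Beyond the cell mix no biological explanation was tested, since the design has 1 group.

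Promoter peaks at neuronal and Hox genes in liver, and at a few muscle genes, may reflect promoter CpG content. Over these lists the mean CpG observed/expected ratio was 0.625 in 56 marked and 0.404 in 23 unmarked genes, a difference of 0.221 (permutation p = 0.0001). The permutation pooled the lists, and marking differed between them: 18 of 22 neuronal, 33 of 39 Hox and 5 of 18 muscle genes. Part of the difference may thus lie between lists and not between marked and unmarked genes of 1 list. Cells of neighbouring tissue in the dissected pools cannot be told apart from promoter CpG content: marked neuronal and muscle genes had 2.04 distal peaks within 50 kb and other marked genes 2.04, a ratio of 1.0002 whose bootstrap 95% interval of 0.613 to 1.45 spans 1 with 23 genes. Beyond neighbouring tissue no biological explanation was tested.

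More distal peaks near erythroid and hepatoblast genes could be pieces of 1 broad promoter domain. Counting only peaks over 10 kb from the gene's own start argued against it as the whole cause, with a ratio to other genes of 2.51 (bootstrap 95% interval 1.5 to 3.85) for erythroid and 1.89 (1.32 to 2.55) for hepatoblast genes. The 99th percentile of domain length was 7929 bp. The domains at the erythroid genes Ank1 (28.4 kb) and Zfpm1 (23.5 kb) reach past 10 kb, so pieces of these may still be counted. Gene density was argued against too, since against density-matched genes the permutation adjusted p was 8.4e-05 for erythroid genes (4.52 against 1.62 peaks, range over 7 alternatives 8.4e-05 to 0.0063) and 0.00042 for hepatoblast genes (3.52 against 1.5, range 0.00042 to 0.0475). Differences in how often these regions are captured or aligned were not tested and stay open. No biological explanation was tested, since the design has 1 group.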
